A study of Homo sapiens with 8 samples.

How the data were processed

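The data comprised 8 one-colour arrays of RNA from A549 cells, 4 from mock-transfected and 4 from MMP19-transfected samples, with groups and replicate numbers taken from the sample titles. Per the file headers, each array was a whole-genome Agilent design annotated on the human build hg18 and read with Feature Extraction 10.7.1.1, while the submitters' processing notes name Agilent Feature Extraction 9.1. The values deposited for each array are spot intensity values on a linear scale, and the processed signal used here is the intensity after the scanner software's background correction, per the file headers. The deposited series matrix holds log2 values of the same arrays for 29807 of the 41000 probes. Set against the scanner values, its columns correlated with the log2 processed signal at r of 0.9997 or more and ran in the same direction. They had medians between 7.80 and 7.82, with an offset that varied between arrays and between the probes of an array. How it was normalized and centred, and how its probes were filtered, is not given in the sources used here. All its columns belonged to the 8 samples.

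Control spots and spots marked as outliers (48 to 115 per array) were left out, and no spot was saturated. Spots of one probe were averaged, and the log2 processed signal was reduced by each array's 75th percentile. Probes were kept when well above background on at least 3 of the 4 arrays of either group, which left 29503 of 41000 probes. Probes were named by accession through a RefSeq gene table of assembly GRCh38.p14, since the files used here pair probes with accessions. A symbol was found for 23958 probes (58.4%), covering 16557 genes, and the other 17042 probes kept the file's identifier. Because the builds of the array and of the table differ, no genome positions are given. The brightest kept probe stood for each gene, which gave 22980 genes, 13332 of them with a symbol.

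Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment), with all 8 arrays and no covariate. A gene was counted as different at an adjusted p below 0.05, and in a second count also at a log2 difference of at least 1. MMP19 was also compared by an exact two-sided permutation test. Before the data were examined, 24 gene lists with 588 genes were set, of which 507 were tested, 66 were on the array but too dim and 15 were not matched. Lists were tested with camera, also of limma, with a preset correlation of 0.01 and adjustment over the lists, with an estimated correlation and with fry beside it. The median of each list was also set among 10000 random lists matched on brightness. Of the 8 lists that passed camera, 6 also passed with an estimated correlation.

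The rule for named genes was fixed before the data were examined. It took MMP19, PTGS2, the 12 largest rises and 12 largest falls among genes with a usable symbol whose groups did not overlap and whose brighter group was well above background on all 4 arrays, and up to 4 members with the smallest p from each list, or 1 where none passed. This gave 85 genes, of which 81 passed the test besides MMP19 and 3 did not. The values of 1 of these genes are not reported here. For a gene not well above background on any array of a group, only a bound on the fold is given, which can equal the measured fold. At least 1 other kept probe did not pass the test for RPL6, THBS1, SLC7A11, FAM13A, COL4A5, ETV5, CDCP1, PTGS1, NDRG1, PFKFB3, BNIP3L, IFIT2, FBLN1, SLC2A3, BNC2, FOXJ1 and MMP19.

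Alternatives were quantile normalization, median centring, other probe filters, every probe, the mean of a gene's probes, the series matrix, slide or replicate number as a block, an intensity trend in the variance prior, and leaving out each array. Normexp background correction (offset 50) had been planned on the mean spot signal, which was not used here. It was run on the median spot signal and local background instead, with quantile normalization or 75th percentile scaling, as an alternative chosen after the data were examined, as was leaving out the 2 arrays of slide 3. The slides were also the scan batches, with 3 arrays each on slides 1 and 2 and 2 arrays on slide 3.

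The fit was tested on simulated data with the real probes' means and SDs for 22980 genes, 200 of them changed. It recovered 56% of the 100 genes changed by 0.5 on the log2 scale and 83% of the 100 changed by 1, with 8 false calls among 147. For the set test, 1 list of 25 genes shifted by 0.5 was found and 0 of 23 unshifted lists. The simulated genes varied independently, so this does not check false calls for lists whose genes vary together. The depth of an array cannot be counted as reads can, and precision rests on the number of arrays and on signal over background.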

Results

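Gene expression was measured in A549 cells, an established human lung adenocarcinoma line with features of alveolar epithelium, after stable transfection with MMP19. MMP19 is a secreted matrix metalloproteinase, a zinc-dependent protease that cleaves components of the basement membrane. The MMP19 group held 4 samples carrying the full-length cDNA, and the mock group held 4 samples carrying the vector without it. The comparison asks which genes differ when these epithelial cells make MMP19, in a study concerned with pulmonary fibrosis. RNA of each sample was labelled with a single dye and hybridised to 1 whole-genome Agilent array. The 75th percentile of the processed signal lay between 830 and 1162 on the 8 arrays, and between 69.0% and 74.7% of the 41000 probes were well above background. The arrays lay on 3 slides, each holding both groups. The labels do not say that the samples of a group came from separate cultures or separately derived lines, so the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

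The transfected gene itself was far higher in every MMP19 sample. The MMP19 probe used for the gene rose by 8.76 on the log2 scale (SE 0.114, n = 4 per group), a 435-fold difference. An exact two-sided permutation test of that probe gave p = 0.0286, the smallest value that 4 against 4 samples allow, and the adjusted p from limma was 1.45e-08. Its processed signal was 302, 304, 298 and 433 in mock replicates 1 to 4, and 147816, 174094, 137554 and 168636 in MMP19 replicates 1 to 4. With slide as a block the difference was 8.78, and within slides 1, 2 and 3 it was 8.87, 8.96 and 8.42. A second MMP19 probe, A_23_P203882, read between 138593 and 152607 in the MMP19 samples and was well above background in 2 of the 4 mock samples, at 144 in mock replicate 3 and 40.6 in mock replicate 4. The log2 difference of A_23_P203882 was 13.05 (SE 1.19), larger than that of the probe used. The remaining probe assigned to MMP19, A_24_P184445, differed by -0.02 (SE 0.253) between the groups, so the probes of the gene disagreed.

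**Figure D1:**
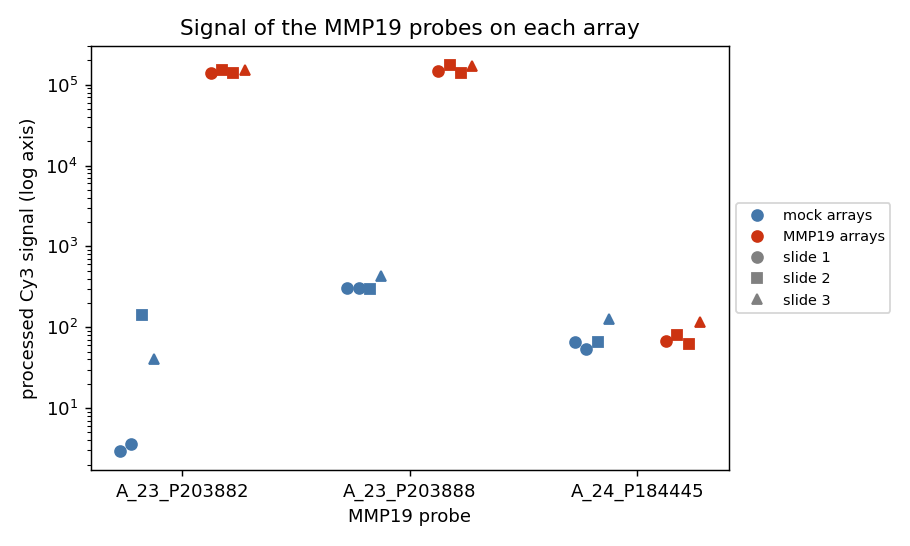
Processed Cy3 signal (log axis) of the 3 probes assigned to MMP19 on each array, with mock arrays in blue, MMP19 arrays in red and the marker shape giving the slide. The used probe A_23_P203888 lies between 298 and 433 on the mock arrays and between 137554 and 174094 on the MMP19 arrays, while A_24_P184445 does not separate the groups.

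Cells carrying MMP19 had higher expression of inflammatory cytokines and chemokines, interferon-stimulated genes and genes of the endoplasmic reticulum stress response. The chemokine CXCL8, which attracts neutrophils, rose 9.21-fold, and the cytokine IL6 rose 6.95-fold. OASL, an interferon-stimulated gene, rose 9.88-fold, and DDIT3, a transcription factor induced by unfolded proteins, rose 8.95-fold. The falls were smaller, the steepest among the named genes on the processed signal being that of SYT6, a synaptotagmin, which was 2.33-fold lower. Of 22980 genes tested, 2239 differed at an adjusted p below 0.05 (limma, Benjamini-Hochberg), 1323 of them higher and 916 lower with MMP19. At least 2-fold differences numbered 102, with 92 genes higher and 10 lower. The median size of a difference among the 2239 genes was 0.39 on the log2 scale, against a median SD within a group of 0.116 for mock and 0.120 for MMP19. In 4569 genes, 19.9% of those tested, the values of the groups did not overlap, where chance gives 2.86%.

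The number of genes passing the test changed when 1 array was left out. It was 1534, 1099, 1357 and 1244 without mock replicate 1, 2, 3 or 4. Without MMP19 replicate 1, 2, 3 or 4 it was 1289, 1112, 2776 and 1052. Leaving out an array also makes the test less able to find differences. With slide as a block 1549 genes passed, 973 higher and 576 lower, and 98 of them differed at least 2-fold. The 2 arrays of slide 3 lay apart from the others on the second principal component, which held 26.2% of the variance, and without them 667 genes passed, 93 of them at least 2-fold, as chosen after the data were examined. The balance of higher and lower genes depended on the filter and the scaling: against 59.1% higher, testing all probes without a filter on dim ones gave 1364 higher and 3218 lower, or 29.8% higher, and centring each array on its median gave 1499 higher and 425 lower, or 77.9% higher. The sizes of the rises of dimmer genes depended on the background correction: after normexp background correction scaled to the 75th percentile, chosen after the data were examined, 715 genes passed, 34 of them at least 2-fold, and the log2 differences of CXCL8, OASL and IL6 were 2.04, 2.06 and 1.51 in place of 3.20, 3.30 and 2.80, still past the threshold.

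Among the 12 largest rises of genes with a usable symbol, besides those above, were CCL5 and CCL20, chemokines for lymphocytes and dendritic cells, and IFI44, an interferon-stimulated gene. None of these was well above background on any mock array. By the bound used, CCL5 was at least 9.68-fold and IFI44 at least 5.54-fold higher with MMP19, and CCL20 was 9.1-fold higher. These bounds set the mean of the MMP19 arrays against the higher of the probe's own signal and the lowest signal among probes well above background on each mock array. For CCL20 the probe's own signal was the higher on each mock array, so 9.1-fold is its measured difference and no lower limit. The bounds leave out the spread between arrays. They hold for the processed signal alone: after normexp background correction scaled to the 75th percentile, CCL5, CCL20 and IFI44 differed by 0.597, 0.557 and 0.118 on the log2 scale and did not pass (adjusted p = 0.199, 0.223 and 0.738), and after normexp with quantile normalization by 0.930, 0.888 and 0.491, which passed. PTX3, a secreted pattern recognition protein, rose by 2.64 on the log2 scale and was well above background on 1 of the 4 mock arrays, but its difference was 0.164 and did not pass after normexp background correction scaled to the 75th percentile (adjusted p = 0.642), and it was 0.542 after normexp with quantile normalization. The interferon-stimulated genes IFIT1 and IFIT2 rose 6.86-fold and 5.80-fold, and the log2 difference of IFIT2 was 1.82 in place of 2.54 after normexp background correction scaled to the 75th percentile. CDH15, a cadherin of muscle cells, rose 8.50-fold (adjusted p = 0.000138), with log2 differences of 3.36, 3.22 and 2.37 within the 3 slides, and 1.15 after normexp background correction scaled to the 75th percentile or 1.42 with quantile normalization. GPHB5, a glycoprotein hormone subunit, rose 5.96-fold (adjusted p = 0.000135), by 2.57 on the log2 scale and by 1.96 after normexp background correction scaled to the 75th percentile.

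Genes of the endoplasmic reticulum stress response rose together. Of 28 tested members 23 rose, or 26 when adjusted over the list alone, and the median log2 difference was 0.77. DDIT3 rose by 3.16 (SE 0.123), HERPUD1, which takes part in the degradation of misfolded proteins, by 2.06 (SE 0.0772), and DNAJB9, a chaperone of the endoplasmic reticulum, by 2.05 (SE 0.0734). SYVN1, a ubiquitin ligase of the same degradation route, rose 2.15-fold. The list shifted upward relative to the other genes (camera, adjusted p = 3.29e-29, and adjusted p = 0.00915 with an estimated correlation). Its median was 0.88, 0.72 and 0.67 within slides 1, 2 and 3, and the adjusted p was 6.1e-27 with slide as a block.

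Cytokines and chemokines controlled by NF-kappaB rose as a group. Of 25 tested members 17 rose, or 20 when adjusted over the list alone, with a median log2 difference of 0.68. CXCL8 rose by 3.20 (SE 0.111), IL6 by 2.80 (SE 0.109) and CCL20 was the member given above that was not well above background on any mock array. ICAM1, a leukocyte adhesion molecule, rose by 1.39 (SE 0.0656), but by 0.595 without passing the test after normexp background correction scaled to the 75th percentile (adjusted p = 0.0916). The shift of the list had an adjusted p of 1.48e-19 (camera, and adjusted p = 0.00915 with an estimated correlation). Within slides 1, 2 and 3 the median was 0.77, 0.65 and 0.47, and the adjusted p was 3.2e-18 with slide as a block.

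Interferon-stimulated genes also rose. Of 25 tested members 15 rose, or 17 when adjusted over the list alone, with a median log2 difference of 0.54. The median was 0.27 after normexp background correction scaled to the 75th percentile and 0.37 after normexp with quantile normalization, where the list still passed. OASL rose by 3.30 (SE 0.114), IFIT1 by 2.78 (SE 0.119), IFIT2 by 2.54 (SE 0.0931) and IFIT3 by 1.83 (SE 0.122). The difference of IFIT3 was 0.837 and did not pass after normexp background correction scaled to the 75th percentile (adjusted p = 0.0585). A second IFIT2 probe gave 2.26 without passing the test. The shift of the list had an adjusted p of 1.26e-15 (camera, and adjusted p = 0.0407 with an estimated correlation). Its median was 0.70, 0.57 and 0.70 within slides 1, 2 and 3, and the adjusted p was 8.42e-16 with slide as a block.

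Genes of the growth factor and immediate-early response rose in 15 of 30 tested members, or 18 when adjusted over the list alone, with a median log2 difference of 0.38. FOSL1, a component of the AP-1 transcription factor, rose 2.25-fold, and AREG, a ligand of the epidermal growth factor receptor, rose 1.80-fold. IGFBP1, which binds insulin-like growth factors, rose 1.81-fold, and DUSP5, a phosphatase acting on ERK, rose 1.73-fold. The immediate-early genes FOS, FOSB, JUN, EGR1, MYC and DUSP1 did not pass (limma, adjusted p between 0.0626 and 0.677). Their log2 differences were -0.84, 1.72, 0.21, 0.44, 0.21 and 0.19, while IER3 and CCN1 rose by 0.33 and 0.61. The shift of the list had an adjusted p of 1.32e-10 (camera, and adjusted p = 0.0497 with an estimated correlation). Its median was 0.26, 0.42 and 0.42 within the 3 slides, with an adjusted p of 2.27e-10 with slide as a block.

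Targets of p53 rose in 10 of 22 tested members, or 12 when adjusted over the list alone, with a median log2 difference of 0.19. GADD45A, a growth arrest gene, rose 2.42-fold, and SESN2, a sestrin that responds to stress, rose 2.32-fold. SESN2 is also a member of the endoplasmic reticulum stress list. The 12 p53 targets that did not pass included BBC3 at -0.12, BAX at -0.03 and DDB2 at 0.07. BTG2, an antiproliferative gene, rose 1.74-fold. MDM2, the ubiquitin ligase of p53, rose 1.38-fold, but its log2 difference was -0.0937 after normexp background correction scaled to the 75th percentile. The shift of the list had an adjusted p of 3.18e-08 (camera, and adjusted p = 0.0497 with an estimated correlation), with medians of 0.23, 0.16 and 0.19 within the 3 slides and an adjusted p of 1.03e-07 with slide as a block.

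Genes of cholesterol synthesis rose in 10 of 23 tested members, or 14 when adjusted over the list alone, with a median log2 difference of 0.23. The enzymes HSD17B7, MVD and MSMO1 rose 1.55-fold, 1.47-fold and 1.42-fold. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose 1.31-fold. The shift of the list had an adjusted p of 1.14e-08 (camera, and adjusted p = 0.0497 with an estimated correlation), with medians of 0.26, 0.19 and 0.19 within the 3 slides and an adjusted p of 1.03e-07 with slide as a block.

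A minority of proliferation genes fell, by small amounts. Of 30 tested members 5 fell, or 9 when adjusted over the list alone, and the median log2 difference was -0.07, or -0.03 with median centring. The value of -0.07 lay at percentile 9.92 of 10000 random lists matched on brightness. CCNE2, a cyclin of S phase entry, was 1.65-fold lower, CCNA2, a cyclin of S and G2 phase, 1.17-fold, and the replication helicase subunits MCM3 and MCM6 were 1.22-fold and 1.16-fold lower. The list had an adjusted p of 0.0126 (camera), and of 0.0252 with slide as a block, with medians of -0.11, -0.11 and -0.03 within slides 1, 2 and 3. The call was lost with adjusted p = 0.0532 with an estimated correlation and with adjusted p = 0.0747 without MMP19 replicate 3. The estimated correlation was -0.005, below the preset 0.01, so a higher correlation did not cause the first of these losses. The call was also lost with adjusted p = 0.146 without a filter on dim probes, and with adjusted p = 0.719 after normexp background correction scaled to the 75th percentile. The falls of CCNA2, MCM3 and MCM6 were lost with slide as a block (adjusted p = 0.071, 0.069 and 0.0798), and in 6, 6 and 8 of the 8 fits that left out 1 array, with adjusted p up to 0.0834, 0.114 and 0.110. After normexp background correction scaled to the 75th percentile, CCNE2, CCNA2, MCM3 and MCM6 did not pass (adjusted p = 0.113, 0.0964, 0.238 and 0.22).

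Integrins and plasminogen activation genes rose in 5 of 20 tested members and fell in 1, or 9 and 1 when adjusted over the list alone, with a median log2 difference of 0.19. That median was 0.00915 after normexp background correction scaled to the 75th percentile and 0.11 without a filter on dim probes, and the list still passed in both. PLAU, the urokinase-type plasminogen activator, rose 1.32-fold, and CDCP1, a transmembrane protein that plasmin cleaves, rose 1.34-fold. ITGB8, an integrin subunit that binds latent TGF-beta, rose 1.36-fold, but its log2 difference was -0.0895 after normexp background correction scaled to the 75th percentile. ITGA1, a subunit of a collagen receptor, was 1.47-fold lower. CDCP1 and ITGA1 did not pass after normexp background correction scaled to the 75th percentile (adjusted p = 0.29 and 0.128). The list had an adjusted p of 0.00943 (camera), of 0.00554 with slide as a block, and lost its call with adjusted p = 0.0532 with an estimated correlation. That correlation was -0.014, below the preset 0.01, so a higher correlation did not cause the loss. The medians of the list within the 3 slides were 0.12, 0.14 and 0.20.

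PTGS2, the inducible cyclooxygenase that starts prostaglandin synthesis, rose 2.60-fold, by 1.38 on the log2 scale (SE 0.141, adjusted p = 0.00118), and a second probe gave 1.20. Its difference was 1.08, 1.56 and 1.49 within slides 1, 2 and 3, with an adjusted p of 0.00876 with slide as a block. PTGS2 and its list had been set beforehand in the knowledge that the study itself followed this gene, so the rise is not independent evidence of its direction. The constitutive cyclooxygenase PTGS1 rose 1.42-fold on the probe used, while its log2 difference was -0.17 after normexp background correction scaled to the 75th percentile and -0.25 on a second probe, and PTGS1 did not pass without the slide 3 arrays (adjusted p = 0.0914) or after normexp with quantile normalization (adjusted p = 0.111). These were the 2 of 21 tested prostaglandin and eicosanoid genes that rose, the same number as when adjusted over the list alone, where 1 gene also fell. The list as a whole did not pass (camera, adjusted p = 0.768).

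**Figure D2:**
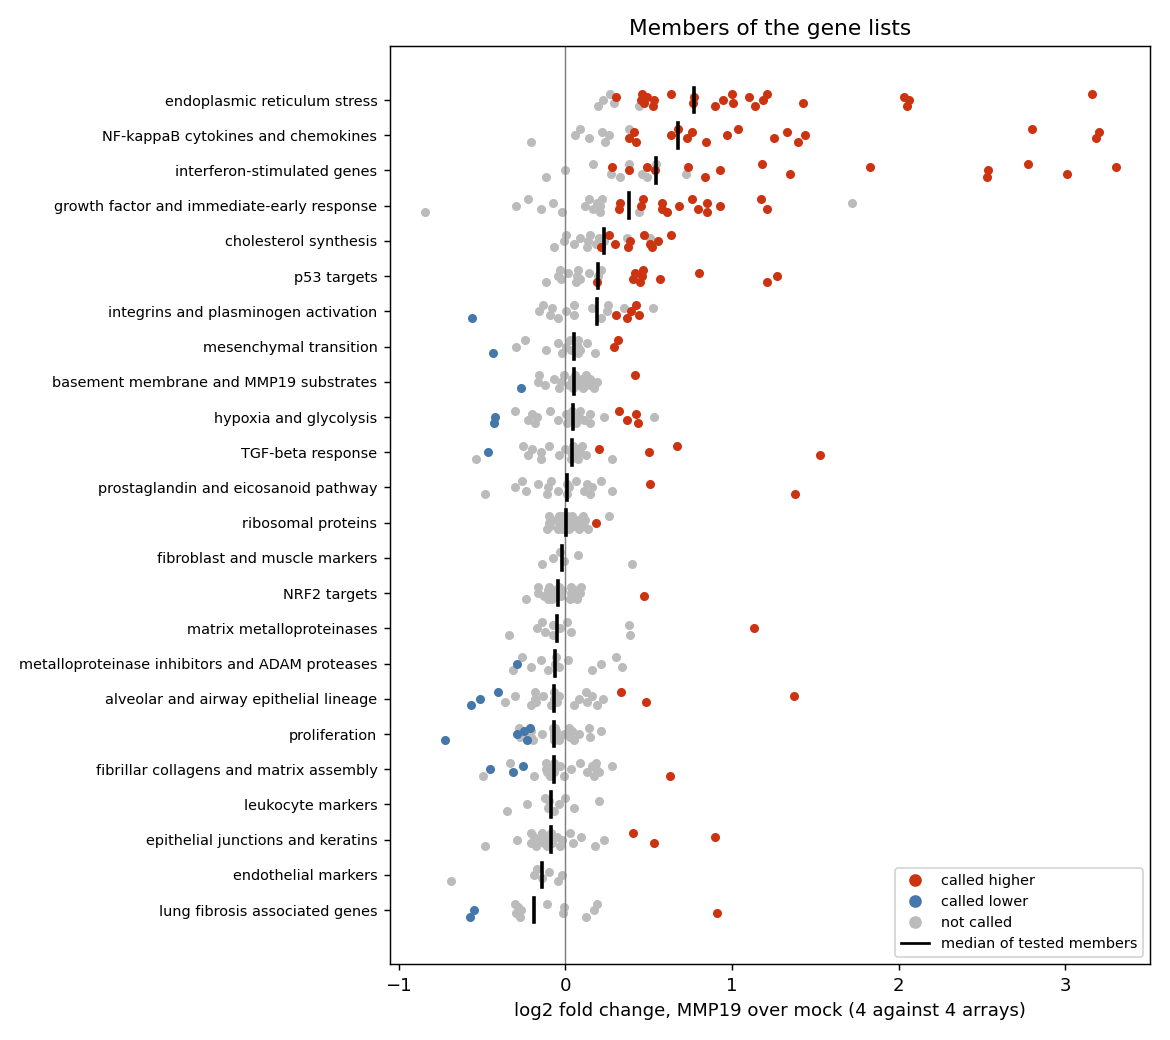
Log2 fold change of MMP19 over mock for each tested member of the 24 gene lists, none of which holds MMP19 itself. Red and blue points are members higher or lower at an adjusted p below 0.05, grey points did not pass, and the black bar is the median, which is highest for endoplasmic reticulum stress at 0.77.

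The other matrix metalloproteinases and their inhibitors mostly did not pass the test. Among 12 tested metalloproteinases besides MMP19, MMP1, an interstitial collagenase, rose 2.19-fold (adjusted p = 0.00164), but its log2 difference was -0.0875 after normexp background correction scaled to the 75th percentile and 0.27 after normexp with quantile normalization. No other member passed, also when adjusted over the list alone, and 3 had an unadjusted p below 0.05, MMP1 among them. Of 14 tested inhibitors and ADAM proteases ADAM19 fell, to 1.23-fold below mock, a call lost after normexp background correction scaled to the 75th percentile (adjusted p = 0.0677) and without the slide 3 arrays (adjusted p = 0.0936), and 2 were higher and 2 lower when adjusted over the list alone. Neither list shifted (camera, adjusted p = 0.912 and 0.732), and for the metalloproteinases the median of -0.05, or -0.22 after normexp background correction scaled to the 75th percentile, and the mean of 0.08 differed in sign.

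Genes of the extracellular matrix went in both directions. Of 23 tested basement membrane genes and MMP19 substrates 1 rose and 1 fell, the same numbers as when adjusted over the list alone, and COL4A5, a type IV collagen chain, was 1.20-fold lower. Of 26 tested genes of fibrillar collagens and matrix assembly 1 rose and 3 fell, or 2 and 4 when adjusted over the list alone, while no tested gene was matched to a chain of type I collagen. Since 9648 of the 22980 genes tested had no symbol, a change of type I collagen was left open. The collagen crosslinking enzyme LOX was not well above background on any mock array and was at least 1.18-fold higher, while its log2 difference was -0.38 after normexp background correction scaled to the 75th percentile. FBLN1, THBS1 and LOXL1, which are matrix proteins and a crosslinking enzyme, were 1.37-fold, 1.24-fold and 1.19-fold lower. The falls of COL4A5, FBLN1, THBS1 and LOXL1 were lost with slide as a block (adjusted p = 0.0994, 0.0691, 0.096 and 0.0832) and, with LOX, in 5 to 7 of the 8 fits that left out 1 array, with adjusted p up to 0.121. After normexp background correction scaled to the 75th percentile these 4 falls did not pass either, with adjusted p between 0.0663 for FBLN1 and 0.182 for LOXL1, and LOX lost its call also after normexp with quantile normalization (adjusted p = 0.604) and with an intensity trend in the variance prior (adjusted p = 0.186). Other probes of COL4A5, FBLN1 and THBS1 did not pass. The lists did not shift (camera, adjusted p = 0.418 and 0.768).

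Epithelial junction and mesenchymal genes showed few differences. Of 25 tested junction and keratin genes the tight junction genes CLDN1, OCLN and CLDN4 rose 1.86-fold, 1.45-fold and 1.32-fold, and when adjusted over the list alone 3 rose and 2 fell. The log2 difference of CLDN4 was -0.00701 after normexp background correction scaled to the 75th percentile, where OCLN did not pass either (adjusted p = 0.152), and CLDN4 did not pass without the slide 3 arrays (adjusted p = 0.0713). Of 18 tested genes of mesenchymal transition 2 rose and 1 fell, the same numbers as when adjusted over the list alone. SNAI1, a repressor of E-cadherin, was 1.35-fold lower, while the E-cadherin gene CDH1 was not higher, at -0.29 (limma, adjusted p = 0.0564). ACTA2, smooth muscle actin, and AXL, a receptor tyrosine kinase, rose 1.22-fold and 1.24-fold, calls that were lost with slide as a block (adjusted p = 0.0519 and 0.0592) and in 4 and 7 of the 8 fits that left out 1 array, with adjusted p up to 0.0588 and 0.083, and after normexp background correction scaled to the 75th percentile (adjusted p = 0.0854 and 0.138). Neither list passed camera (adjusted p = 0.912 and 0.689), although the mesenchymal median lay at percentile 95.4 of the matched random lists.

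Genes of the TGF-beta response rose in 4 of 24 tested members and fell in 1, or 5 and 3 when adjusted over the list alone. INHBA, a subunit of activin A, rose 2.88-fold and was well above background on 2 of the 4 mock arrays, but its log2 difference of 1.53 became 0.0258 after normexp background correction scaled to the 75th percentile (adjusted p = 0.941) and 0.383 after normexp with quantile normalization. KLF10, a transcription factor induced by TGF-beta, rose 1.59-fold and TGFB2 itself 1.41-fold, while ID1, an inhibitor of differentiation, was 1.38-fold lower. TGFB2 did not pass after normexp background correction scaled to the 75th percentile (adjusted p = 0.106), nor KLF10 without the slide 3 arrays (adjusted p = 0.0819). The list did not pass camera (adjusted p = 0.689) but passed fry (adjusted p = 0.0403), which does not compare a list with other genes. Of 14 tested genes associated with lung fibrosis, GREM1, an antagonist of bone morphogenetic proteins, rose 1.88-fold, but its log2 difference of 0.91 became 0.434 and did not pass after normexp background correction scaled to the 75th percentile (adjusted p = 0.141). TERT, the catalytic subunit of telomerase, was 1.49-fold lower and FAM13A 1.46-fold lower, calls lost without the slide 3 arrays (adjusted p = 0.0819 and 0.0668). The call of FAM13A was also lost with median centring (adjusted p = 0.0585) and in 4 of the 8 fits that left out 1 array, with adjusted p up to 0.0725, and a second probe gave -0.10. When adjusted over the list alone 2 of the fibrosis genes rose and 5 fell. The median of that list was -0.06 after normexp with quantile normalization, and its value of -0.19 on the processed signal lay at percentile 0.21 of 10000 random lists matched on brightness, while its shift did not pass camera (adjusted p = 0.497).

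Hypoxia, antioxidant and lineage genes did not pass camera as lists (adjusted p = 0.418, 0.732 and 0.912), although the hypoxia list passed after normexp background correction scaled to the 75th percentile (adjusted p = 0.0134, median 0.0152 in place of 0.0434) and its median lay at percentile 97.1 of the matched random lists. Of 27 tested hypoxia and glycolysis genes 4 rose and 2 fell, or 7 and 3 when adjusted over the list alone. NDRG1 and BNIP3L, both induced by hypoxia, rose 1.35-fold and 1.34-fold, although a second BNIP3L probe gave 0.03, and the glucose transporter SLC2A3 and the glycolytic regulator PFKFB3 were 1.34-fold and 1.35-fold lower. SLC2A3 and PFKFB3 did not pass after normexp background correction scaled to the 75th percentile (adjusted p = 0.153 and 0.111) or as the mean of their probes (adjusted p = 0.0523 and 0.0615), nor PFKFB3 without the slide 3 arrays (adjusted p = 0.0815). Among 24 tested NRF2 targets the cystine transporter SLC7A11 rose 1.38-fold, also when adjusted over the list alone. That call was lost with slide as a block (adjusted p = 0.0543) and in 6 of the 8 fits that left out 1 array, with adjusted p up to 0.0789, and its other probes gave -0.08 and 0.00. Of 25 tested alveolar and airway genes 3 rose and 3 fell, or 4 and 4 when adjusted over the list alone. LAMP3, a lysosomal protein of type II alveolar cells, rose 2.58-fold and was well above background on 1 of the 4 mock arrays, but its log2 difference of 1.37 became 0.000942 after normexp background correction scaled to the 75th percentile (adjusted p = 0.998) and 0.368 after normexp with quantile normalization. The transcription factor ETV5 rose 1.40-fold, a call lost in 3 of the 8 fits that left out 1 array, with adjusted p up to 0.0533. The transcription factors SOX2 and FOXJ1, of airway progenitors and ciliated cells, were 1.48-fold and 1.43-fold lower, although a second FOXJ1 probe gave 0.05. After normexp background correction scaled to the 75th percentile, SLC7A11, ETV5 and FOXJ1 did not pass (adjusted p = 0.0567, 0.235 and 0.19).

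Markers of other cell types showed no difference that passed the test. For 10 tested leukocyte markers, 7 endothelial markers and 6 fibroblast and muscle markers, limma gave 0 differing genes over all genes and 0 when adjusted over the list alone. At an unadjusted p below 0.05 the leukocyte list had 1 higher and 1 lower gene, and the other lists had 0. The members with the smallest p were FCER1G at -0.23 (adjusted p = 0.111), CLDN5 at -0.69 (adjusted p = 0.204) and PDLIM3 at -0.14 (adjusted p = 0.481). Neither camera (adjusted p = 0.732, 0.418 and 0.912) nor fry (adjusted p = 0.695, 0.396 and 0.725) gave a shift. Among 33 ribosomal protein genes RPL6 rose 1.14-fold, a call lost with slide as a block (adjusted p = 0.0726) and in 7 of the 8 fits that left out 1 array, with adjusted p up to 0.0972, and after normexp background correction scaled to the 75th percentile (adjusted p = 0.138). When adjusted over the list alone limma gave 0 ribosomal genes, against 2 at an unadjusted p below 0.05, and the list did not pass camera (adjusted p = 0.689). The ribosomal list did pass as higher after both normexp corrections, with medians of 0.0457 with quantile normalization and 0.054 with 75th percentile scaling (adjusted p = 0.0387 and 6.67e-05), and its median of 0.002 without them lay at percentile 98.3 of the matched random lists.

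The 12 largest falls among genes with a usable symbol that were well above background on all mock arrays were spread over different functions. Of these 12 only SYT6 was at least 2-fold lower. Over all genes tested 10 were, so the others of these 10 did not meet the rule for named genes. After SYT6, with a log2 difference of -1.22 (SE 0.179), came CXXC4, an inhibitor of Wnt signalling, at -0.96 (SE 0.133), PRR15L at -0.95 and RNF43, another Wnt inhibitor, at -0.93 (SE 0.21). The phospholipase PLCH1 fell by 0.91, DGAT2, an enzyme of triglyceride synthesis, by 0.88 and the zinc finger protein BNC2 by 0.81. S1PR5, a receptor for sphingosine-1-phosphate, fell by 0.79 with an adjusted p of 0.000709. CCNE2, TOB1, PALMD and ZNF99 were 1.65-fold, 1.65-fold, 1.64-fold and 1.63-fold lower. RNF43 and ZNF99 lost the call with slide as a block (adjusted p = 0.0682 and 0.0914), and RNF43, TOB1 and ZNF99 lost it in 6, 5 and 6 of the 8 fits that left out 1 array, with adjusted p up to 0.0902, 0.0858 and 0.125. After normexp background correction scaled to the 75th percentile, SYT6, CXXC4, PRR15L, BNC2, PALMD and ZNF99 did not pass, with adjusted p between 0.0515 for PRR15L and 0.166 for ZNF99, and after normexp with quantile normalization SYT6 and CXXC4 differed by -0.31 and -0.34. PRR15L and PLCH1 did not pass without the slide 3 arrays (adjusted p = 0.0596 and 0.0642).

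**Figure D3:**
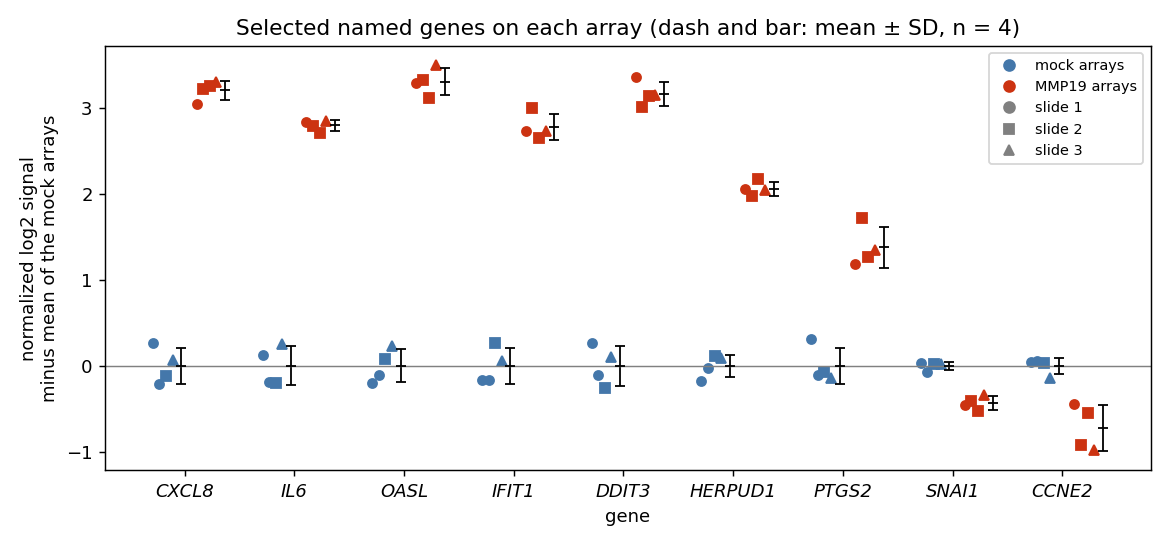
Normalized log2 signal of 9 named genes on each array, relative to the mean of the mock arrays, with mock in blue, MMP19 in red, marker shape by slide, and mean ± SD (n = 4) beside the points. CXCL8, IL6, OASL, IFIT1, DDIT3, HERPUD1 and PTGS2 lie above the mock arrays on all 4 MMP19 arrays, and SNAI1 and CCNE2 lie below them.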

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

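The tests of slide, of leukocytes, of the transfected line, of carry-over and of the immediate-early genes were chosen after the results they concern were seen.

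The number of differing genes was compared over the 35 splits of the 8 arrays into 4 and 4. Of these, 1 split, the real one, gave as many as 2239 genes, and the highest of the others gave 0 (limma). The other split with most genes at an unadjusted p below 0.05 had 4564, against 6284 in the real split. For differences of at least 2-fold, 1 of the 35 splits, again the real one, reached 102 genes, and the highest other gave 0. Every other split mixes mock and MMP19 arrays on both sides, so the group difference itself widens the spread within each side and makes calls unlikely. The splits therefore cannot exclude chance differences between cultures or lines, since the samples of a group may be technical repeats.

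In 16 of 174 groups of 4 values 1 array stood apart, its gap to the nearest array taking most of the group's range. Chance alone gives about 1 in 20, or 8.70 groups. Mock replicate 4 stood apart in 7 of them, with a share of the range of 0.886 for PTX3, 0.905 for GPHB5, 0.989 for S1PR5, 0.865 for CCNE2, 0.945 for ID1, 0.874 for FCER1G and 0.917 for the MMP19 probe A_24_P184445. MMP19 replicate 4 stood apart for the same MMP19 probe, at 0.913. Mock replicate 1 stood apart for PTGS2 at 0.849, where it read -1.01 against -1.45 to -1.39 in the other mock arrays, for SESN2 at 0.905, for ITGB8 at 0.844 and for TERT at 0.847. Mock replicate 2 stood apart for CLDN4 at 0.964 and SNAI1 at 0.877, mock replicate 3 for ZNF99 at 0.834 and MMP19 replicate 3 for MCM3 at 0.865.

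The arrays of slide 3 deviated together: the differences of mock replicate 4 and MMP19 replicate 4 from the other arrays of their groups correlated across genes at r = 0.60, where genes are not independent replicates. Dim probes alone are argued against, since the correlation was 0.449 across the brightest 25% of genes. The median deviation of 8 immediate-early genes lay at percentile 0 of 10000 matched random lists, and 5 of the 8, FOS and EGR1 among them, were lower on both arrays. These genes were picked after FOS and EGR1 had been seen to deviate, so a shared difference in culture or harvest and one in hybridisation or scanning cannot be told apart. No biological explanation was tested, since slide 3 matches no group, and without its arrays 667 genes differed, 93 of them at least 2-fold.

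The second MMP19 probe, A_23_P203882, read 144 in mock replicate 3 and 40.6 in mock replicate 4, against 2.95 and 3.56 in mock replicates 1 and 2. Carry-over of MMP19 RNA could have caused this, and would then raise the brighter MMP19 probe as well, by about 156 scaled signal units in mock replicate 3. That probe instead differed by -32.4 from the mean of mock replicates 1 and 2 (SD 33.8), which argues against carry-over in mock replicate 3. In mock replicate 4 the excess was 102 where 43.9 was needed, but the MMP19 probe that did not respond to the transgene also read 128 there, against a mean of 65.1 in mock replicates 1 and 2, and carry-over and the deviation of slide 3 cannot be told apart. No biological explanation was tested.

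The joint rise of endoplasmic reticulum stress, NF-kappaB and interferon-stimulated genes was weighed against 4 explanations. A difference between slides is argued against by the lowest median of the 3 lists within any slide, 0.475 on the log2 scale. A trend with brightness is argued against by the 3 medians, each at percentile 100 of 10000 lists matched on brightness. Leukocytes in the MMP19 cultures are argued against by 0 of 10 tested leukocyte markers passing as higher in limma (1 at an unadjusted p below 0.05), with TYROBP at -0.07, CD68 at 0.05 and CD14 at -0.11. Expression of MMP19 and any other property of the transfected line, such as its selection or the load of a highly expressed secreted protein, cannot be told apart, since the groups hold 0 further lines with MMP19 or with another secreted protein.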

How the results depend on the processing

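Normexp background correction on the median spot signal and leaving out slide 3 were chosen after the data were examined, and the planned normexp on the mean spot signal was not run. The MMP19 log2 fold change stayed between 7.26 and 8.88 and past the threshold under every alternative run. Each took 1 probe for the gene or the mean of its probes. Taken singly, probe A_23_P203882 gave 13.05 and A_24_P184445 gave -0.02, so the range does not cover the disagreement between probes. The number of lists passing stayed between 7 and 9 for the alternative values, arrays and blocks, 6 with an estimated correlation and 9 with fry in place of camera. The list that most often lost its call was proliferation, with adjusted p = 0.146 without a filter on dim probes. Lists gained were the ribosomal proteins (adjusted p = 0.0387 and 6.67e-05 after normexp with quantile normalization and with 75th percentile scaling), hypoxia and glycolysis (adjusted p = 0.0134 after the latter) and, with fry, the TGF-beta response (adjusted p = 0.0403).

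The number of differing genes was 4582 without a filter on dim probes, which tests 32642 genes and gave 1364 higher and 3218 lower, 715 after normexp scaled to the 75th percentile, and 667 without the slide 3 arrays. It lay between 1052 and 2776 when 1 array was left out, the highest without MMP19 replicate 3. Under the other alternatives, apart from the replicate block, it lay between 1549 and 2898. The count of at least 2-fold differences was 38 and 34 after normexp with quantile normalization and with 75th percentile scaling, and between 73 and 130 otherwise. Both normexp alternatives changed the spot signal and the background correction along with the offset of 50, and no fit varied the offset alone. The causes of the changes in these counts were not tested.

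Normexp scaled to the 75th percentile moved the median log2 difference of all genes from -0.02 to -0.12. Under it the log2 difference of 6 named genes turned negative without passing the test: MMP1 -0.0875, LOX -0.38, CLDN4 -0.00701, PTGS1 -0.17, MDM2 -0.0937 and ITGB8 -0.0895. MMP1, CLDN4, MDM2 and ITGB8 lay above the median of all genes there, -0.12, and LOX and PTGS1 lay below it. On the processed signal the mock means of these 6 genes lay between -7.47 and -3.80 on the log2 scale, relative to the 75th percentile. Under this setting the medians of endothelial, fibroblast and muscle, and leukocyte markers moved from -0.142, -0.021 and -0.084 to -0.356, -0.300 and -0.241. Those of endoplasmic reticulum stress and cholesterol synthesis went from 0.770 and 0.232 to 0.758 and 0.252. The cause of the negative signs was not tested. A further 36 of the 84 lost their call there, INHBA, LAMP3, CCL5, CCL20, IFI44 and PTX3 among them with log2 differences between 0.000942 and 0.597. Of 1757 values of the 84 named genes other than MMP19 under alternatives, 1529 kept direction and side of the threshold, 222 lost the call and 6 turned. For 36 genes both held in every alternative that tested them, and 7 of the 84 were not tested where all 8 arrays had to be well above background. The alternative that tested every probe scored each gene on its used probe, so it could not show disagreement between probes. NDRG1, BNIP3L and IFIT2 count among the 36, although another kept probe of each did not pass. With a block for slide 71 of the 84 kept their call or its absence.

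Mock and MMP19 samples share replicate numbers, but the deviations of same-numbered samples correlated at 0.13, -0.01, 0.12 and 0.60, so the numbers do not pair the samples, and only mock replicate 4 correlated best with its own number. With a replicate block 1237 genes differed, 94 of them at least 2-fold, and 8 lists passed. Signal over background limits the values: 29 differing genes were not well above background on any array of 1 group and have only a bound.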

Other observations

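The 5 gene lists below were added after the results of the earlier lists were seen, and before the values of their own members were looked at.

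Genes of the translocon, which carries new proteins into the endoplasmic reticulum, and of the coats of secretory vesicles rose with MMP19 in 11 of 30 tested members, with a median log2 difference of 0.19. SEC24D, a cargo adaptor of the COPII coat, rose by 1.32 on the log2 scale (adjusted p = 3.67e-05), and SSR3, a subunit of the translocon-associated complex, rose 1.57-fold (adjusted p = 0.00569). SEC23B, SEC24A and SEC61A1, of the same coat and of the translocation channel, rose by 0.43, 0.44 and 0.41 on the log2 scale. The list shifted upward (camera, adjusted p = 2.43e-10 over the 5 lists, and adjusted p = 0.00364 with an estimated correlation), which is consistent with the hypothesis that the secretory pathway rises along with the stress genes of the endoplasmic reticulum. Aminoacyl-tRNA synthetases, several of which are targets of the stress factor ATF4, were higher in 6 of 19 tested members, fewer than the share set beforehand as the bar. GARS1 rose 1.68-fold and WARS1 1.45-fold, and the list passed camera (adjusted p = 0.000424) but not with adjusted p = 0.107 with an estimated correlation.

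The other lists did not pass the tests of the hypothesis that the interferon-stimulated genes rise with a full interferon response, which stays open. Of 17 tested class I antigen presentation genes, limma gave 0 differing, against 4 higher at an unadjusted p below 0.05, with B2M at 0.24 (adjusted p = 0.0593). That list leaned upward without passing (camera, adjusted p = 0.0736). Of 12 interferon genes on the array 4 were tested and 0 passed in limma, against 2 at an unadjusted p below 0.05. IFNL1 was at 1.37 and IFNL2 at 0.54 (limma, adjusted p = 0.0751 and 0.108), while IFNA4 and IFNE were at -0.09 and -0.12. A test that does not pass does not show that these genes stayed level. Cytosolic heat shock genes did not rise as a group: 1 of 16 tested members was higher, HSPA6 at 0.68, while HSPA1A and HSPA1L fell, at -0.62 and -0.43, and the list shifted downward (camera, adjusted p = 0.0272, lost with adjusted p = 0.384 with an estimated correlation).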
